A study of Oryza sativa with 6 samples.

How the data were processed

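Total RNA of panicle primordia from plants grown in a paddy field was measured on 1-colour Agilent rice arrays, with Cy3-labelled RNA made from 0.2 µg of total RNA, per the labels' protocols. The deposited files hold 1 scanner output per sample, made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Processed signal intensity had been background-subtracted and detrended within each array, per the file headers, and no normalization between arrays had been applied. The mean spot intensity and median local background intensity, and flags for signal above background, saturation and outliers, came from the same deposited files. The deposited series table of log2 values matched the scanner values after quantile normalization (correlation at least 0.9999 on every array, slope 1.01 to 1.02). Its column medians all lay between 8.94036 and 8.94172, it had no centring per gene, its direction was that of the signal, and how the authors made it is not given in the sources used here.

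Groups came from the sample descriptions, with 3 replicates each that the design text calls biological. What separated the replicates (plants, plots or days) is not stated, so p-values measure the spread between these samples. Of 45151 spots, 1417 were controls and were left out, leaving 42477 probes, 41908 of them with a rice RAP locus for 29690 loci. Of the rest, 510 were microRNA probes and 59 had neither kind of name. Across the arrays, 307 spots flagged as non-uniform or as population outliers were set to missing. The log2 processed signal minus each array's 75th percentile was used, spots of a probe were averaged, and a probe was tested where it was well above background on all 3 arrays of at least 1 group. Where a gene had several probes, the brightest stood for it. Of 6672 genes with several tested probes, these differed in sign in 1240, including 1 called gene. The lines were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 22877 genes, adjusted p under 0.05). Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, for lists of at least 5 tested genes. Figures were drawn with matplotlib 3.10.9 in Python.

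The design, the 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Members of 5 lists came from RAP loci and those of 23 from patterns on the array's own gene descriptions, because the gene table given (assembly ASM3414082v1) shares no identifiers with the array. Gene names are therefore those of the array design, or symbols of the fixed lists. Chromosomes are those in the array annotation, and no positions or genome build were used. The pattern for core histones also caught linker H1 genes and replacement variants, that for jasmonate caught potassium channels, that for gibberellin caught some ribosomal proteins, and the member of the anther list entered as ZEP1 is described on the array as zeaxanthin epoxidase. The rule named the heading date genes called and, whatever their result, genes that included OsMFT1, Hd3a and Ehd1; a further item is not reported here. It added the 8 largest rises and 8 largest falls among called genes with a description, measured on all 6 arrays without overlap. It also took up to 4 called genes per list and up to 4 each way among genes measured in 1 line only. It gave 23 tested genes, 22 of them called. Other genes in the text were chosen after their values were seen.

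On simulated data with the real means and spreads of 22865 genes in the OsGATA6-AM against ZH11 comparison and 200 changed genes, 83% of genes changed by 3 on the log2 scale and 0% of those changed by 1 were recovered. The simulation drew arrays independently and so left out the axis that the real arrays share. That simulation also called 9 unchanged genes beside the genes changed by 3. Alternatives covered background correction, scaling, the series table, filters, outlier spots, probe rules, the variance prior, blocks for replicate number and slide, leaving out each array, thresholds and the correlation in camera. Scan time coincided with slide, so no separate fit was run for it.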

Results

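Transcript levels were measured in panicle primordia, the young inflorescences of rice (Oryza sativa), collected at stages In2 to In3 of panicle development. The 2 groups were wild-type ZH11, a japonica cultivar, and an OsGATA6-AM line, called AM3 in the sample titles. Each had 3 arrays and no treatment. OsGATA6 is named after the GATA family of zinc finger transcription factors. Each sample was labelled with a single dye and hybridised to its own Agilent rice array of 45151 spots. The 75th percentile of the processed signal lay between 2377 and 3485 on the 6 arrays, and no spot was saturated. Of the spots, at most 70.9% were well above background on ZH11 replicates 1 and 2, which shared slide 1. The share was at least 79.2% on each array of slide 2, which held ZH11 replicate 3 and all 3 OsGATA6-AM arrays. The number of arrays limits the precision. No probe carries the name OsGATA6 in the array files or the gene table used here, so its own transcript was not analysed here and the line labels have no check of that kind.

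The comparison of the lines asks which genes differ in expression between OsGATA6-AM and wild-type primordia. The genes past the test included large, near on-or-off differences and a pair of nearby genes from the same family. Os12g0555300 and Os12g0555500 on chromosome 12, which encode proteins of the probenazole-inducible PBZ1 family of pathogenesis-related proteins, rose 10.6-fold and 7.51-fold. Their log2 fold changes were 3.41 (SE 0.18, adjusted p = 0.00216) and 2.91 (SE 0.19, adjusted p = 0.00459). A retrotransposon gag gene, Os12g0428300, was well above background on all 3 OsGATA6-AM arrays and on no ZH11 array, at least 30.9-fold higher (adjusted p = 0.00205). In the other direction, the lipolytic enzyme gene Os06g0725100 of the GDSL family was well above background only in ZH11, at least 16.4-fold higher there (adjusted p = 0.00147). The homeodomain-like gene Os01g0873000 was likewise measured only in ZH11, at least 18.9-fold higher (adjusted p = 0.0107). With slide as a block, Os01g0873000 no longer passed (adjusted p = 0.0669), although its log2 difference of -4.71 was as large as without it. These bounds set the mean of the bright group against the detection floor of the dim arrays, and they hold for the processed signal only. With normexp background correction, which adds an offset that shrinks differences of dim genes, the log2 fold changes of Os12g0428300, Os06g0725100 and Os01g0873000 were 2.60, -1.65 and -1.90, and all 3 passed (adjusted p = 0.00456, 0.0222 and 0.0293).

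In all, 81 of 22877 genes tested passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 62 higher and 19 lower in OsGATA6-AM. Each of the 81 differed by at least 1.12 on the log2 scale, without overlap between the groups. Of these genes, 29 were well above background in OsGATA6-AM only and 2 in ZH11 only, and 35 on all 6 arrays. The same imbalance held over all genes tested, with 354 above background in OsGATA6-AM only and 5 in ZH11 only, and 2 of the 3 ZH11 arrays were on the slide with fewer spots above background. The array descriptions gave no function for 40 of the 81. At an unadjusted p of 0.05 there were 5615 genes, and the groups did not overlap in 25.5% of tested genes, against 10% by chance. That excess was not particular to the lines: ZH11 replicate 1 with OsGATA6-AM replicates 1 and 2, set against the other arrays, gave 9590 genes at an unadjusted p of 0.05 and 4229 called. Each remaining split gave 0 called genes and 19 to 674 at an unadjusted p of 0.05 (limma). With slide as a block, 26 genes passed, 17 of them among the 81. Values within slide 2, here and for the genes and lists described next, set OsGATA6-AM against ZH11 replicate 3 alone, a single array assumed to vary like the others. The share of called genes that were higher was 76.5%, and ranged over the alternatives from 26.9% with no filter on dim probes to 96.2% with slide as a block. It was 59.6% with normexp background correction (31 higher and 21 lower), 49.6% on slide 2 alone and 94.7% at an adjusted p under 0.01. Leaving out 1 array gave 54.9% without ZH11 replicate 1 and 74.0% to 93.3% without each of the others. The count was 9204 without ZH11 replicate 1 and 10, 123, 15, 13 and 23 without ZH11 replicate 2, ZH11 replicate 3 and OsGATA6-AM replicates 1, 2 and 3.

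Among genes measured on all 6 arrays, the further rises named by the fixed rule had descriptions of different kinds. Os10g0432200, an ABC protein of subfamily E, a family that works in ribosome recycling, rose by 2.46 on the log2 scale (SE 0.20, adjusted p = 0.0125). The neighbouring glucosyltransferase genes Os07g0510400 and Os07g0510500 on chromosome 7 rose by 2.41 (SE 0.18) and 1.67 (SE 0.20). The MATH-domain gene Os10g0429400 rose by 2.03 and the reverse transcriptase gene Os08g0511200 by 1.35. A protein kinase gene, Os10g0200000, rose 2.75-fold by its brightest probe, while its other probe had a log2 fold change of -0.52. Within slide 2 the log2 differences of these genes were 2.15, 2.60, 1.86, 2.16, 1.49 and 1.52 in the order given. With slide as a block none of the 6 passed (adjusted p from 0.0562 to 0.174). With normexp the log2 fold changes were 2.20, 1.64, 0.76, 1.68, 1.31 and 0.90, and Os07g0510500 and Os10g0200000 did not pass (adjusted p = 0.0898 and 0.0823).

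Falls among genes measured on all 6 arrays included 2 transcription factors. The MADS-box gene Os08g0299600, described as AGL15-like, fell by 2.61 on the log2 scale (SE 0.28, adjusted p = 0.0354), and WRKY transcription factor 74, Os09g0334500, fell by 1.67 (SE 0.19, adjusted p = 0.0379). The wound-induced WI12 gene Os03g0299600 fell by 2.09 (SE 0.26), and Os02g0133400, with an SMC domain of chromosome maintenance proteins, fell by 2.43 (SE 0.21). Smaller falls were those of the aspartic peptidase gene Os07g0603500, by 1.91, the Bet v I family gene Os06g0562200, by 1.38, and the TPR-like gene Os03g0680500, by 1.35. Within slide 2 the differences were -2.87, -1.90, -2.61, -2.53, -1.80, -1.40 and -1.30, and with slide as a block none of the 7 passed (adjusted p from 0.0562 to 0.174). With normexp the fall of Os02g0133400 was smaller, with a log2 fold change of -1.21 (adjusted p = 0.0307).

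Further genes were dim in ZH11 and measured on all OsGATA6-AM arrays. The family 17 glycoside hydrolase gene Os07g0539100 was at least 35.6-fold higher (adjusted p = 0.0197), the phytosulfokine peptide hormone precursor gene Os06g0633300 at least 3.66-fold (adjusted p = 0.0379) and the sulfotransferase gene Os04g0526300 at least 3.09-fold (adjusted p = 0.00444). The anionic peroxidase gene Os04g0688200 also rose (adjusted p = 0.0399). Its fitted log2 fold change of 2.43 is uncertain in size, since it was well above background on 1 of 3 ZH11 arrays. With normexp the log2 fold changes of Os04g0688200, Os06g0633300 and Os04g0526300 were 0.38, 0.23 and 0.17 and none passed (adjusted p = 0.164, 0.411 and 0.430), while Os07g0539100 had 2.89 (adjusted p = 0.0473). With slide as a block Os04g0526300 passed (adjusted p = 0.0485), and Os07g0539100, Os06g0633300 and Os04g0688200 did not (0.131, 0.0871 and 0.168), with log2 differences of 5.77, 2.71 and 1.95. Over the 81 genes the median ratio of the difference with slide as a block to that without it was 1.02. These genes were chosen by a fit that included ZH11 replicate 3, which favours a ratio near 1. The ratio therefore cannot say whether slide plays a part in the lost calls. The largest rises of all, chosen after their values were seen, were those of the adjacent loci Os04g0166000 and Os04g0165900, at least 94.1-fold and at least 129-fold higher by the processed signal, whose descriptions give no function. With normexp their log2 fold changes were 4.11 and 4.35, and both passed (adjusted p = 0.000790 and 0.00281). Also chosen in that way, the cytochrome P450 gene Os06g0639800, the glycine-rich protein gene Os07g0511100 and the F-box gene Os10g0567900 rose too. Each was well above background on 1 of 3 ZH11 arrays, so their fitted log2 fold changes of 5.26, 5.66 and 4.89 are uncertain in size, and with normexp they were 3.03, 2.63 and 3.09.

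**Figure D1:**
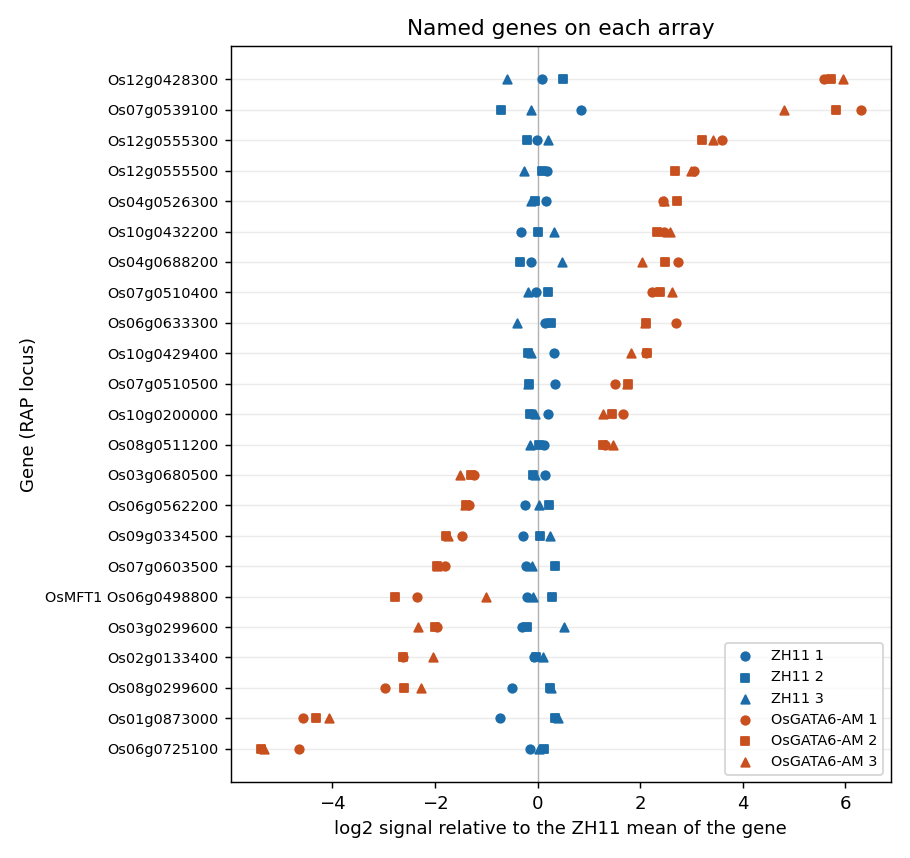
Signal of the 23 genes named by the fixed rule on each of the 6 arrays, as log2 signal relative to the ZH11 mean of the gene (x axis), with a row per RAP locus (y axis), blue for ZH11, orange for OsGATA6-AM and a marker shape per replicate. In each row the 3 OsGATA6-AM points lie on the same side of the 3 ZH11 points. Rows are ordered by fitted log2 fold change, from Os06g0725100, at least 16.4-fold higher in ZH11, to Os12g0428300, at least 30.9-fold higher in OsGATA6-AM. Their points in the dimmer line were not well above background. The order is not one of these bounds, which are larger for Os01g0873000 and Os07g0539100. With normexp the log2 fold changes of Os06g0725100 and Os12g0428300 were -1.65 and 2.60.

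Genes of the heading date and florigen list, which also holds clock genes, were as a list lower in OsGATA6-AM. Of its genes, 0 passed limma's test by itself. Of 16 tested members of the heading date and florigen list, 13 had a fold change below 0, 3 were lower and 0 higher at an unadjusted p of 0.05, and 0 passed adjusted over the list alone. The median centred level of the list was -0.07, 0.30 and 0.65 in ZH11 replicates 1 to 3 and -0.18, -0.20 and -0.21 in OsGATA6-AM. The list lay 0.50 below the other genes on the log2 scale (camera, adjusted p = 0.0390). With an estimated correlation the adjusted p = 0.689, and within slide 2 the shift was -0.66 (adjusted p = 0.0261, from 1 ZH11 array). OsMFT1 (Os06g0498800, chromosome 6), of the phosphatidylethanolamine-binding protein family that includes florigen, had a mean of -3.71 ± 0.25 in ZH11 and -5.76 ± 0.93 in OsGATA6-AM (SD, log2 relative to the 75th percentile, 3 arrays each). Its log2 fold change was -2.05 (SE 0.46), lower on 3 of 3 OsGATA6-AM arrays, and missed the threshold (adjusted p = 0.144, 0.0628 adjusted over the list alone). The photoperiod regulator Hd1 (Os06g0275000) had -1.15 (SE 0.34, adjusted p = 0.174), with ZH11 replicate 1 at -2.71, against -1.75 and -1.47 in replicates 2 and 3 and -3.24, -3.22 and -2.92 in OsGATA6-AM. RCN1 (Os11g0152500), of the same protein family, had 2.30 (SE 1.08, adjusted p = 0.226) and was well above background on 1 ZH11 array, and with normexp it had 0.42. The florigen gene Hd3a and its activator Ehd1 were not tested, as both were well above background on 0 arrays. Some clock genes of the list varied widely within a line. In OsGATA6-AM replicates 1 to 3, OsLHY had 1.26, 0.65 and 4.25 and OsGI 3.67, 3.38 and 1.71. Other members did not, such as OsMADS51 with 2.14, 2.09 and 2.14. Whether time of day at sampling plays a part in the list shift was not tested. The call on the list was lost without ZH11 replicate 3 (adjusted p = 0.0805), with normexp (adjusted p = 0.132) and with the main axis of variation within the lines as a covariate (adjusted p = 0.0666).

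Histone genes, many of which are expressed mainly while DNA is copied, formed the list with the smallest adjusted p. Of 47 tested, 45 had a fold change above 0, 31 rose when p was adjusted over the list alone, and 0 passed over all genes (limma, 34 at an unadjusted p of 0.05). The list lay 0.94 above the other genes (camera, adjusted p = 3.02e-10), with adjusted p = 0.689 with an estimated correlation, and 1.34 above them within slide 2. Examples, chosen after their values were seen, were the H3 genes Os12g0415800 with 2.25 (SE 0.36) and Os11g0155900 with 1.75 (SE 0.42), and the H2B gene Os01g0153300 with 1.08 (SE 0.28). The list also held the linker histone H1 genes Os03g0799000 with 0.84, which is among the 31, and Os04g0253000 with -0.40. Replacement variants, which are not tied to DNA copying, did not all move alike. The H3.3 genes Os03g0390600 and Os06g0130900 had 0.37 and 0.19. The H2A.F/Z gene Os10g0418000 had means of 3.39 in ZH11 and 4.49 in OsGATA6-AM. That rise (SE 0.47) was larger than the median log2 fold change of the list, 1.04. None of these variants is among the 31. Histone genes are near-identical copies, so single members are uncertain. The median centred level of the list was 0.12 in ZH11 replicate 1, against -0.77 and -0.95 in replicates 2 and 3 and 0.75, 0.62 and 0.27 in OsGATA6-AM.

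Genes of cytosolic ribosomal proteins also lay higher in OsGATA6-AM as a list, and leaf photosynthesis genes lower. Of 149 ribosomal protein genes, 126 had a fold change above 0 and 34 passed an unadjusted p of 0.05, all higher, while 0 passed by limma over all genes or adjusted over the list alone. The list shift was 0.28 (camera, adjusted p = 1.71e-05, and adjusted p = 0.689 with an estimated correlation), and 0.37 within slide 2. The gene of the 60S protein L44 (Os07g0523100) had 0.92 (SE 0.19). Of 44 photosynthesis genes, 36 had a fold change below 0, with 7 lower and 1 higher at an unadjusted p of 0.05 and 0 passing by limma, over all genes or adjusted over the list alone. Their shift was -0.67 (camera, adjusted p = 0.00153, and adjusted p = 0.689 with an estimated correlation), and -0.96 within slide 2. With no filter on dim probes the call on this list was lost (adjusted p = 0.0640). The photosystem I subunit XI gene Os12g0420400 had -2.27 (SE 0.96). The median centred level of these photosynthesis genes was -0.37 in ZH11 replicate 1, 0.71 and 0.62 in replicates 2 and 3, -0.49 and -0.49 in OsGATA6-AM replicates 1 and 2, and 0.28 in replicate 3. The ribosomal list had -0.03, -0.23 and -0.23 in ZH11 and 0.36, 0.20 and -0.09 in OsGATA6-AM. In both lists the medians of the lines thus overlapped. As many lists as between the lines, or more, were called in 7 of the 10 splits of the 6 arrays, the real split included (camera).

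**Figure D2:**
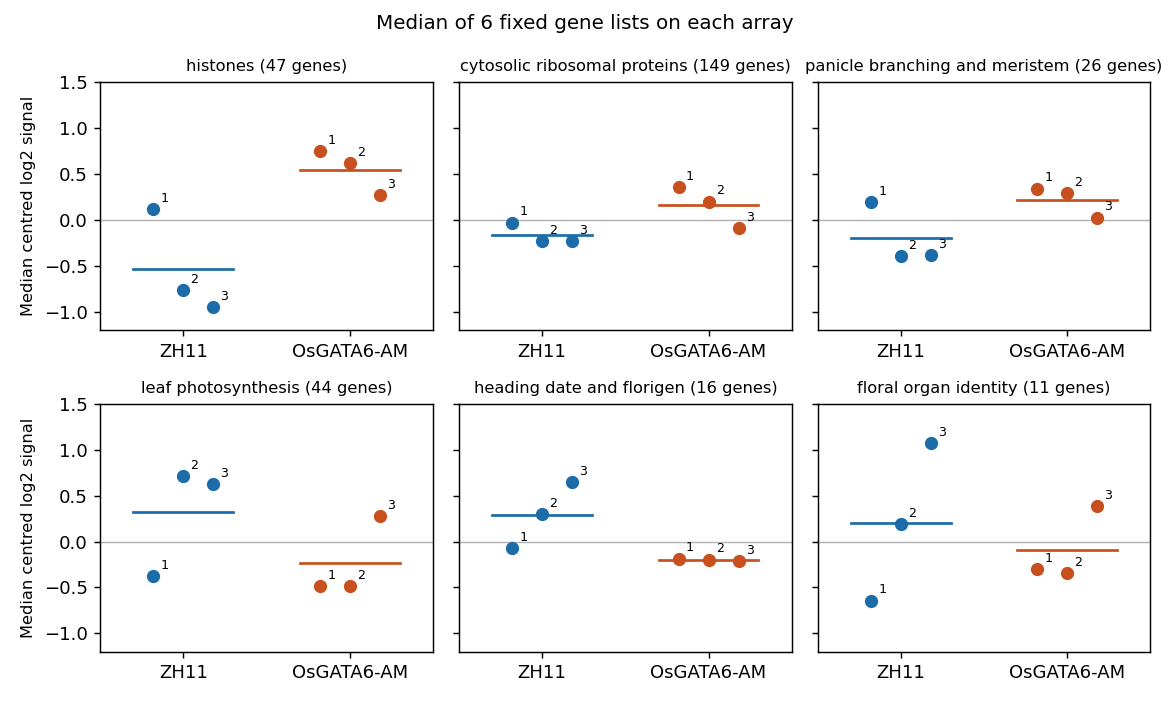
Median centred log2 signal (y axis) of 6 fixed gene lists on each array, with numbered points for the replicates, a bar at the mean of 3 arrays, blue for ZH11 and orange for OsGATA6-AM (x axis). ZH11 replicate 1 lies nearer to OsGATA6-AM than the other ZH11 arrays for the histones, at 0.12 against -0.77 and -0.95.

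Genes of panicle branching and meristem identity did not pass as a list. Their shift was 0.33 over 26 tested genes (camera, adjusted p = 0.0750), and 0.50 within slide 2 (adjusted p = 0.0349, from 1 ZH11 array). When adjusted over the list alone, 2 members rose and 0 fell, and 0 passed over all genes (limma, 8 higher and 2 lower at an unadjusted p of 0.05). These were FZP (Os07g0669500), a promoter of spikelet meristem identity, with 1.86 (SE 0.39), and the kinase gene OsPID (Os12g0614600), with 1.13 (SE 0.18). OsSPL14 (Os08g0509600), a regulator of branching, had -0.60 (SE 0.17), short of the threshold. Floral organ identity genes had a shift of -0.57 over 11 genes (camera, adjusted p = 0.262), with 0 called by limma and 2 lower at an unadjusted p of 0.05, and -1.38 within slide 2 (adjusted p = 0.00215, from 1 ZH11 array). ZH11 replicate 3 stood apart in that list, with a median centred level of 1.07 against -0.64 and 0.19 in replicates 1 and 2.

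Of the lists fixed for transcription factors, GATA factors had 0 of 15 called by limma, with 3 higher and 1 lower at an unadjusted p of 0.05 (camera, adjusted p = 0.656). All MADS-box genes had 1 of 22 called, the AGL15-like gene named above, with a shift of -0.50 (adjusted p = 0.0565), and -0.98 within slide 2 (adjusted p = 0.000448, from 1 ZH11 array). Of 49 WRKY genes 1 was called, and adjusted over the list alone 4 fell and 2 rose. WRKY67 (Os05g0183100), with -1.65 (SE 0.22), was among the falls. Of 45 homeobox genes 0 were called over all genes by limma, with 11 higher and 4 lower at an unadjusted p of 0.05, and 2 fell and 1 rose adjusted over the list alone. The 48 auxin response genes had a shift of 0.33 (adjusted p = 0.0531), with 2 higher and 1 lower adjusted over the list alone. The 2 higher, Os03g0633500 and Os04g0519700, lay near background in ZH11, with means of -8.83 and -8.68, and with normexp their log2 fold changes were 0.14 and -0.05 (adjusted p = 0.615 and 0.841), so neither rise is secure.

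The remaining tested lists did not pass. Their camera adjusted p was 0.0565 for expansins and xyloglucan endotransglucosylases, 0.167 for cyclins with replication licensing and 0.167 for peroxidases with laccases. It was 0.200 for anther and meiosis genes, 0.284 for transposons, 0.307 for heat shock proteins, 0.386 for jasmonate, 0.388 for WRKY, 0.388 for defence genes and 0.388 for inflorescence meristem MADS-box genes. The homeobox list had 0.0565, and 0.886 was reached by gibberellin, by terpene synthesis and by lipid transfer with cuticle, and 0.968 by sugar and starch metabolism. Within slide 2, against 1 ZH11 array, the shift was 0.83 for expansins (adjusted p = 0.0326) and -0.59 for terpene synthesis (adjusted p = 0.0349). Adjusted over the list alone, 1 gene rose and 1 fell among expansins and likewise among lipid transfer genes, and 1 defence gene rose. Over all genes, 1 peroxidase and 1 transposon gene were called, Os04g0688200 and Os12g0428300 named above. Median, mean and test differed in sign for the WRKY, defence, terpene and lipid transfer lists. Seed storage, with 4 tested genes, and the cytokinin, ethylene-responsive and SPL lists, with 0, had too few for a test.

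The 6 arrays did not separate by line along their main axis of variation. The first principal component held 71.9% of the variance, with ZH11 scores of -26.6, 84.4 and 87.8 and OsGATA6-AM scores of -73.2, -65.3 and -7.18. Across 22865 genes, ZH11 replicate 1 correlated at 0.983 with OsGATA6-AM replicates 1 and 2, and at 0.963 and 0.952 with ZH11 replicates 2 and 3. Genes are not independent replicates, so these values describe the arrays only.

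**Figure D3:**
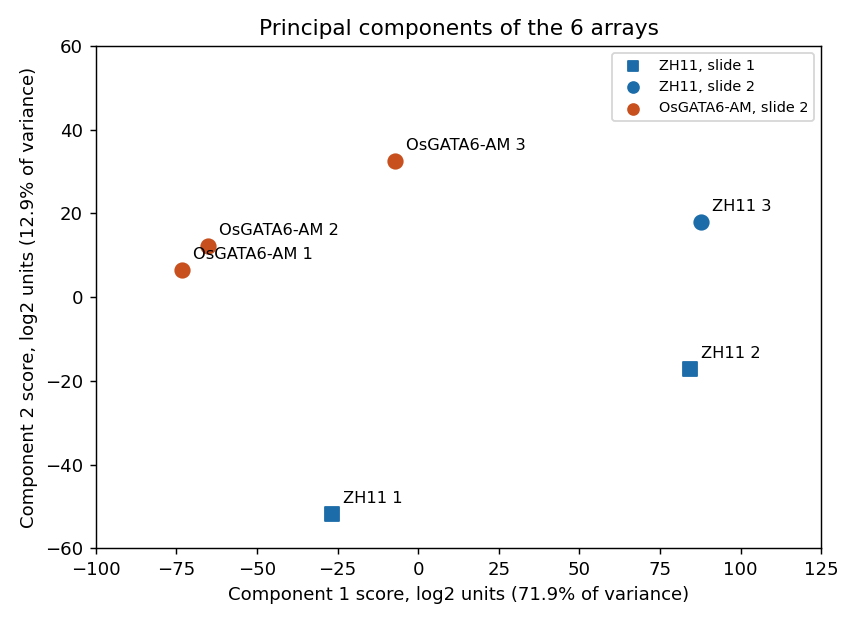
Scores of the 6 arrays on the first (x axis, 71.9% of variance) and second (y axis, 12.9%) principal components of log2 signal, with blue for ZH11, orange for OsGATA6-AM, squares for slide 1 and circles for slide 2. ZH11 replicate 1 lies at -26.6 on the first component, among the OsGATA6-AM arrays, and ZH11 replicates 2 and 3 lie at 84.4 and 87.8. On the second component the slide 1 arrays lie at -51.7 and -17.2, and those of slide 2 at 6.41 to 32.4.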

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

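The residual-component covariate and the fit on slide 2 alone were chosen after seeing the data; the rest was planned. The 81 genes became 52 with normexp, 124 with quantile normalization, 238 with no filter on dim probes (64 higher, 174 lower), 12 when only probes above background on all 6 arrays were kept, 48 with a trended robust prior, 19 at adjusted p under 0.01, 26 with slide as a block and 252 on slide 2 alone, both against ZH11 replicate 3 alone. Leaving out 1 array gave 10 to 9204 genes. Adding the first component of the within-line residuals gave 10381, where fold changes stay equal by construction and p-values are too small because the component came from the same values. Normexp moved the median fold change of all genes from 0.06 to -0.09.

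With replicate number as a block, 49 genes and 8 lists passed. Deviations of same-numbered arrays correlated at 0.583, -0.477 and 0.388. ZH11 replicates 1 and 3 correlated best with their own number, and ZH11 replicate 2 did not (0.673 with OsGATA6-AM replicate 3). Deviations within a line depend on each other, so these values cannot decide whether the numbers pair the samples.

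The 4 lists became 7 with normexp, 11 with no filter, 9 with every probe by itself, 9 with slide as a block, 10 on slide 2 alone, 4 to 10 without 1 array, and 0 with an estimated correlation (0 at an unadjusted p of 0.05 in camera). The estimated correlation between genes was 0.524 in the histone list, 0.503 in the ribosomal, 0.516 in the photosynthesis and 0.0571 in the heading list. All lie above the preset 0.01, which takes the genes of a list as nearly independent. The cause was not tested for the other changes. The histone, ribosomal, photosynthesis and heading lists kept their direction in all 21 alternatives, with shifts of 0.74 to 1.40, 0.18 to 0.54, -1.09 to -0.42 and -0.66 to -0.42. Some lists that were not called kept theirs too, such as GATA factors (0.02 to 0.33) and WRKY (-0.27 to -0.08), while heat shock proteins did not. A constant direction over the same arrays thus does not set the 4 lists apart. Of 22 named genes called, 5 passed with the slide block. All 22 passed without ZH11 replicate 1, but that fit called more genes over all than any other that left out 1 array. With as many arrays fitted, 15 passed without ZH11 replicate 3, and 3 without ZH11 replicate 2 or without OsGATA6-AM replicate 1. The number of arrays alone thus does not account for the lost calls. Os12g0555300, Os12g0428300 and Os06g0725100 passed in each alternative that tested them. OsMFT1 had -2.57 to -1.44 and passed in 2 of 20 (adjusted p 0.0128 to 0.496). The OsGATA6 transcript has no alternatives, as it was not analysed here. Signal near background limits the genes measured in 1 line only, since slide 1 had fewer spots above background.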

Other observations

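Some genes at the ends of the first principal component, picked after the values were seen, varied widely among arrays of the same line. The seed storage gene for globulin 1 (Os03g0663800) had log2 levels of -6.03, 2.70 and 3.29 in ZH11 replicates 1 to 3, and -7.39, -4.97 and -2.95 in OsGATA6-AM. A dehydrin gene (Os11g0454300), of a family induced by water loss, had -0.99, 3.15 and 3.93 in ZH11 and -0.15, -1.71 and 2.90 in OsGATA6-AM. A B-box gene (Os02g0606200) had -0.67, 4.43 and 4.06 in ZH11 and -1.44, -0.54 and 3.80 in OsGATA6-AM. At the other end lay a cell wall invertase gene (Os04g0413500), with -1.72, -4.31 and -3.72 in ZH11 and 0.07, 0.20 and -0.83 in OsGATA6-AM. Apart from these, the clock gene OsLHY (Os08g0157600) had 1.39, 3.84 and 3.31 in ZH11 and 1.26, 0.65 and 4.25 in OsGATA6-AM, with a log2 fold change between the lines of -0.80 (SE 1.07).

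Probes without a rice locus, 187 of them tested and 179 of these for microRNAs, gave 0 calls between the lines by limma, with 26 at an unadjusted p of 0.05.

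The tests on the spread within lines and on chromosome position were chosen after the result was seen; those on slide for the called genes, on splits and on miR528 were planned. The reading of 3 tests was also changed after a first run had shown their values. The leaf tissue test was first read as excluded, because 45.5% lies under the bound of 50%, and was then left open because its exact interval reaches past that bound. The test on chromosome segments was first read as excluded and was then left open because 12 met both bounds as they had been written. For miR528 the value set against the prediction was first the smaller of both precursor probes, -1.46. It was then that of the probe above background, 0.0043. The reading, that the predicted rise was not seen, stayed the same.

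The first pattern is the set of genes that differ between the lines. In the 123 genes called from OsGATA6-AM against ZH11 replicates 1 and 2 alone, ZH11 replicate 3, on the OsGATA6-AM slide, had a median position of 0.359, where 0 is the other ZH11 arrays and 1 is OsGATA6-AM. It lay on the OsGATA6-AM side in 54 of the 123. The choice of genes by ZH11 replicates 1 and 2 itself favours a left-out ZH11 array nearer to OsGATA6-AM. Slide and line therefore cannot be told apart for part of these genes, and the position cannot say how far slide plays a part. Of the 10 splits of the 6 arrays, 2 gave at least the 81 genes of the real split, and the highest other split gave 4229, which points to a structure of the samples. For lists, 7 splits reached the real 4 and the highest other gave 9; the 10 splits are too few for a share under 0.05, and a difference between the lines stays open as the biological explanation.

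The second pattern is that arrays of the same line differ as much as the lines do. Slide accounts poorly for it along the first component. The gap between slide means there was 0.391 of the gap between ZH11 replicates 1 and 2, which share a slide. The second component, with 12.9% of the variance, did split the slides. ZH11 replicates 1 and 2 on slide 1 had -51.7 and -17.2. ZH11 replicate 3 had 17.9 and OsGATA6-AM had 6.41, 12.2 and 32.4, so a smaller part for slide stays open. A wrong line label on ZH11 replicate 1 is argued against too: among 38 genes at least 4 apart between OsGATA6-AM and ZH11 replicates 2 and 3, it lay on the OsGATA6-AM side in 39.5% (exact 95% interval 24.0% to 56.6%), where a wrong label needs over 90%. Leaf tissue may contribute, since 45.5% of 44 photosynthesis genes were at least 1 higher in ZH11 replicates 2 and 3 than in replicate 1, with an exact interval of 30.4% to 61.2%. That interval also falls short of the 80% set for leaf tissue, which by the reading used for the label would argue against it. The step of 1, however, lies near the median difference of the list, 0.89, so the share decides little. Stage or time of day at sampling stay open too. Both exact intervals take genes as independent, while the estimated correlation in the photosynthesis list was 0.516, so they may be too narrow.

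The third pattern is that called genes lie near each other on chromosomes: 16 of 81 had another called gene within 10 tested genes, against a mean of 5.5 in 10000 random draws. Leaving out neighbours of the same description, 12 remained, which 3.34% of draws reached, at the edge of the middle 95% of draws. Descriptions were compared as text, so unlike labels that give no function counted as different. Os12g0543800, with no hit, and Os12g0547600, a hypothetical protein, are such a pair. Segments that differ between the lines therefore may or may not be involved. As many genes with the largest differences within ZH11 gave 8, between the bounds set for general co-expression of neighbours. Both explanations stay open, and a segment from another genetic background is a hypothesis only. The neighbours included Os04g0165900 with Os04g0166000, and Os12g0555300 with Os12g0555500.

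The labels do not expand the letters AM. A hypothesis is that the transgene may be an artificial microRNA carried in the miR528 precursor. The prediction set for it was a rise of at least 1 in both precursor probes. The 3' precursor probe, well above background on all 6 arrays, differed by 0.0043 on the log2 scale, so the predicted rise was not seen. The 5' probe differed by -1.46 and was not well above background on any array. The part of the precursor that such a transgene would keep is not known here, so these probes cannot decide whether the line carries an artificial microRNA.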
